A study of Mus musculus with 14 samples.

How the data were processed

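Hearts of male wild-type C57BL/6 mice were sampled at 12 and 68 weeks of age. The deposited data comprised 8 RNA-seq libraries of total heart RNA, 4 per age, and region lists from CUT&RUN for H3K27me3, a histone mark laid down by Polycomb repressive complex PRC2 and associated with gene silencing. CUT&RUN cuts and releases DNA at sites bound by an antibody. Each age had 2 H3K27me3 libraries and 1 input library.

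The deposited RNA values were whole-number counts of reads per gene, not normalized, per the file headers and the values themselves. Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2 and DESeq2 were among the tools in the submitters' processing notes, which gave neither their roles nor their order. Whether strand or reads with several matches entered the counts was not given in the sources used here, so values of genes with near-identical copies or antisense partners are uncertain. Of 49315 genes, 174 had no symbol. The deposited per-library counts were identical to the series table in each of the 8 libraries. Every column of that table was assigned to a sample by the name its label gives.

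The deposited region lists gave positions, linked genes and a score per region, called enrichment by the authors, with no stated scale. Trim Galore 0.6.5, Bowtie2 2.4.2, SAMtools 1.14, Picard 2.26.2 and MACS3 3.0.0b1 were also named in the submitters' processing notes. Per the labels, each list was compiled from the CUT&RUN libraries of 1 age, and the region names in the files call every region unique to its age. The lists therefore hold only differences between the ages, and no value per library, so no replicate error could be given for them. How replicates were combined, and which rule linked genes to regions, were not given in the sources used here.

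The labels name mm10 for the series. Of 2479 links whose gene was in the count tables, 20.6% placed the region on the gene's span in those tables, and the median gap of the others was 113 kb. The build of the region coordinates was therefore not established, and region positions are printed as the deposited lists give them, without a build. Gene positions come from the count tables and match mm10 by label. The planned links by distance to a gene start or gene body were not made, and the authors' own links were used.

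Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment over 15947 genes at an adjusted p of 0.05. The model held age alone. Log2 fold changes are 68 minus 12 weeks. The SE printed with them was computed as the size of the log2 fold change divided by the square root of F, and is approximate. Levels are given as CPM, counts scaled to the normalized library size, as mean ± SD over 4 libraries. The summed airway markers, Ucp1, Scgb1a1, Bpifa1 and Sftpc are given instead as CPM of the total counts of each library. The libraries held 23599296 to 34599121 counts, and the common biological coefficient of variation was 0.139. The labels do not state that the 4 libraries of an age came from separate mice, and p-values measure the spread between these libraries. Every pair of libraries of 1 age differed by more than sampling noise, with a chi-square per degree of freedom of at least 17.3.

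The 45 gene lists, 29 of pathways and 16 of cell types, were fixed before the data were examined. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the 45 lists. Overlaps between linked genes and changed genes were tested with two-sided Fisher's exact tests, adjusted over 10 tests, with all genes tested by edgeR as background, and by permutation against 10000 random draws of genes matched on expression, or on genomic span and expression. Genes are not independent replicates, so these p-values describe the lists, not the mice.

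Tests were tried on simulated counts drawn from the means, dispersions and library sizes of the 8 libraries, with 200 changed genes. In this simulation of 68 against 12 weeks, over 15667 tested genes, edgeR recovered 47.3% of genes changed 1.5-fold, 76.2% of those changed 2-fold and 94.9% of those changed 4-fold. False calls made up 4.14% of 145 calls. A list of raised genes was called and 0 of 40 lists of unchanged genes were. Each gene was drawn independently, so the simulation could not test list calls where genes vary together.

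Named genes followed a rule fixed before the data were examined. It took the 12 largest changes in each direction among called genes with a mean log2 CPM of at least 0 whose libraries separated by age, leaving out predicted genes and antigen receptor segments. It also took up to 4 members of each list with the smallest p, a fixed set of 19 genes on H3K27me3, glutamine and cardiac stress, the 10 highest-scoring regions of each list, and 10 genes linked to a region at 1 age only. The rule took 219 genes, of which 82 were called, and the text prints part of them, favouring called genes. Values of a few genes are not reported here, though these genes stayed in every test and count. That selection within the rule, the airway marker lists, and the naming of Ucp1, Sftpc and the full set of called genes linked to 12-week regions, were made after values were seen.

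Alternatives were DESeq2 1.42.0, limma-voom, other normalizations and filters, stricter thresholds, a replicate block, and leaving out each library in turn. Fits with airway markers as a covariate, or restricted to 4 libraries alike in airway counts, and DESeq2 on the genes that edgeR kept, were added after seeing the data.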

Results

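Gene expression was compared between hearts of mice aged 12 and 68 weeks, with 4 RNA-seq libraries per age, and related to regions that the authors list as unique to either age in H3K27me3 CUT&RUN. The series title concerns glutamine, cardiac ageing and H3K27me3. Library totals ran from 23599296 to 31662601 counts at 12 weeks and from 28842059 to 34599121 at 68 weeks. Mitochondrial genes took 7.41% to 12.1% of the counts.

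At 68 weeks, 256 genes were higher and 195 were lower of 15947 tested. The potassium channel gene Kcnk1 (chromosome 8, 125995170 to 126030685, mm10 by label) rose from 0.558 ± 0.216 CPM at 12 weeks to 5.47 ± 0.758 at 68 weeks, with a log2 fold change of 3.27 ± 0.25 (adjusted p = 0.000335, edgeR). The immunoglobulin heavy chain gene Ighg2c rose from 1.91 ± 0.0832 CPM at 12 weeks to 11.6 ± 1.2 at 68 weeks, with a log2 fold change of 2.60 ± 0.10. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitors p16 and ARF, rose from 0.0976 ± 0.012 CPM at 12 weeks to 0.467 ± 0.115 at 68 weeks (log2 fold change 2.21 ± 0.31, adjusted p = 0.00907), at a very low level in both ages, and was not called with airway markers in the model (2.16 ± 0.42, adjusted p = 0.0749). Ddc, which encodes aromatic amino acid decarboxylase, fell from 4.5 ± 0.598 CPM at 12 weeks to 0.894 ± 0.0786 at 68 weeks (log2 fold change -2.32 ± 0.15, adjusted p = 0.00015).

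Other large increases were seen for the endothelin gene Edn3 (2.43 ± 0.35), the ryanodine receptor gene Ryr1 (2.4 ± 0.40), Klk1b26 (2.28 ± 0.24), Lypd6 (1.99 ± 0.29), the phosphodiesterase gene Pde11a (1.79 ± 0.24), the lectin gene Cd209f (1.90 ± 0.20), Ano5 (1.78 ± 0.13), Dpp6 (1.78 ± 0.28), the cadherin gene Cdh22 (1.76 ± 0.18), Cds1 (1.60 ± 0.11) and Tmprss13 (1.55 ± 0.18), all as log2 fold change ± SE. Klk1b26 belongs to a family of near-identical genes, so its count is uncertain. Large decreases included genes of fatty acid elongation and desaturation, namely Elovl3 (-3.58 ± 0.81), Elovl6 (-2.61 ± 0.53) and Scd1 (-2.29 ± 0.49). These were highest in 12-week replicate 4, at 4.33, 34.2 and 638 CPM against at most 1.55, 16.6 and 441 CPM in the other 3 libraries of that age, and this library also held the most Ucp1. Without it their log2 fold changes were -2.79, -1.98 and -1.91 (adjusted p = 0.0759, 0.0415 and 0.0675, edgeR). The beta3-adrenergic receptor gene Adrb3 (-2.14 ± 0.41), the FGF21 co-receptor gene Klb (-2.34 ± 0.46), Acvr1c (-2.23 ± 0.41), Adtrp (-3.00 ± 0.54), Apoc1 (-2.49 ± 0.42), Aspg (-2.60 ± 0.49), Clstn3 (-2.19 ± 0.46) and the B cell regulator Pax5 (-2.35 ± 0.39) also fell. Without 12-week replicate 4, Klb (-2.07) and Clstn3 (-1.90) were no longer called (adjusted p = 0.058 and 0.0746, edgeR), and the others of these stayed called. Of 12 adipocyte markers, 4 fell, and the list's median log2 fold change was -1.66 (adjusted p = 2.97e-09 by camera and 0.486 with an estimated correlation). When airway markers entered the model, Edn3 (2.24 ± 0.44), Lypd6 (1.87 ± 0.33) and all of the named decreases but Adtrp (-3.37 ± 0.58) and Ddc (-2.48 ± 0.17) were no longer called. Elovl3, Elovl6 and Scd1 then had log2 fold changes of -4.05 ± 0.85, -2.83 ± 0.57 and -2.17 ± 0.50. The other decreases no longer called had values from -2.88 (Aspg) to -2.01 (Pax5). In the 4 libraries with the most airway counts, 3 at 12 weeks against 1 at 68 weeks, Elovl3, Elovl6 and Scd1 had -1.38, -1.49 and -1.02. In the 4 with the fewest, 1 against 3, these genes had -5.95, -3.86 and -3.53.

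**Figure D1:**
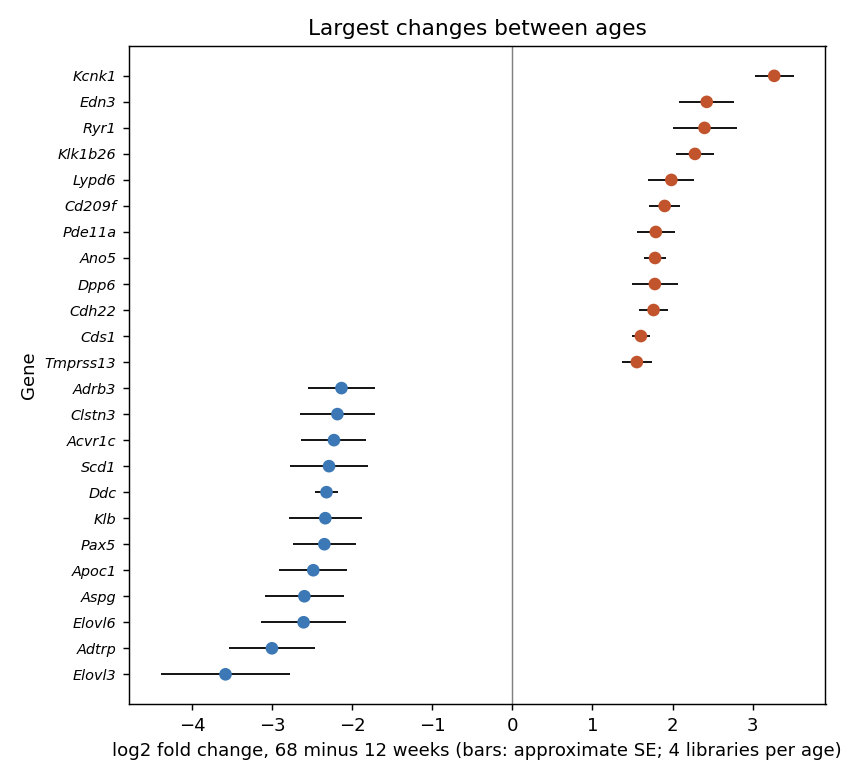
Log2 fold change, 68 minus 12 weeks (x axis), of the 12 genes with the largest increase and the 12 with the largest decrease (y axis) among called genes with a mean log2 CPM of at least 0, predicted genes and antigen receptor segments left out, with approximate SE as bars, 4 libraries per age. Values run from -3.58 for Elovl3 to 3.27 for Kcnk1.

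All 451 called genes separated the ages completely, where chance gives 2.86% of genes. That follows largely from the threshold, since the largest unadjusted p called was 0.00141, and it adds no independent evidence. With library size alone as the normalization, 176 genes were higher and 248 lower, which turned the excess of higher genes into an excess of lower ones. DESeq2 called 557 higher and 455 lower on the genes that edgeR kept, a setting chosen after seeing the data. With its own filter, which left 16415 of 30702 genes with an adjusted p, it called 568 higher and 439 lower. The airway settings gave fewer genes than the 256 and 195. Higher genes numbered 119, 117 and 140 without 12-week replicate 1, 2 or 3, and 140, 169 and 119 without 68-week replicate 2, 3 or 4. Lower genes numbered 55, 81, 74 and 125 without 12-week replicate 1, 2, 3 or 4, and 82, 68 and 52 without 68-week replicate 1, 2 or 4.

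Transcripts of airway epithelium differed widely between the heart libraries. The first principal component held 52.8% of the variance, and its leading genes included the airway secretory genes Bpifa1, Scgb1a1, Scgb3a2 and Muc5b and the ciliated cell regulator Foxj1. By CPM of the total counts, the 20 airway markers summed to 1806, 958 and 562 CPM in 12-week replicates 1 to 3 and to 1074 CPM in 68-week replicate 3. They summed to 29.5 CPM in 12-week replicate 4 and to between 2.95 and 3.47 CPM in 68-week replicates 1, 2 and 4. Of the 20 markers, 0 were called higher or lower with age by edgeR, the median log2 fold change of the 8 secretory markers being -2.42. With the airway markers in the model, edgeR called 61 genes higher and 14 lower, of which 59 and 13 were among the 256 and 195. Among the 4 libraries with the fewest airway counts, 1 against 3, edgeR called 10 genes higher and 23 lower, and among the 4 with the most, 3 against 1, 4 higher and 1 lower.

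**Figure D2:**
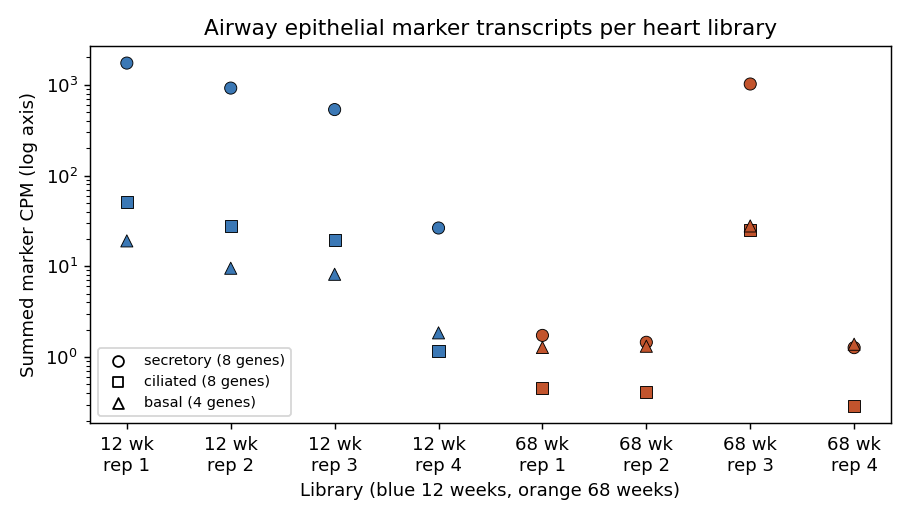
Summed CPM, by total counts, of airway secretory, ciliated and basal cell markers (y axis, log scale) in each of the 8 heart libraries (x axis), blue for 12 and orange for 68 weeks. The 20 markers together reached 1806 CPM in 12-week replicate 1 and 1074 CPM in 68-week replicate 3, against 2.95 CPM in 68-week replicate 4.

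Of the measured PRC2 genes and the H3K27 demethylase genes and cofactors, Uty alone was called in RNA, close to the threshold. Of 13 measured PRC2 genes, 0 were called by edgeR over all genes or adjusted over the list alone. The methyltransferase genes had log2 fold changes of -0.15 ± 0.056 (Ezh1) and -0.25 ± 0.11 (Ezh2), and the core subunits of -0.0084 ± 0.10 (Eed) and -0.066 ± 0.05 (Suz12). Among 9 demethylase genes and cofactors, Uty fell by a log2 fold change of -0.18 ± 0.04 (adjusted p = 0.0491), while Kdm6a (-0.087 ± 0.064) and Kdm6b (-0.058 ± 0.076) were not called. Among 20 PRC1 genes, 2 rose and 1 fell over all genes and adjusted over the list alone, those that rose being Rybp (0.32 ± 0.064) and Pcgf5 (0.27 ± 0.055). Uty (-0.19 ± 0.057), Rybp (0.31 ± 0.09) and Pcgf5 (0.24 ± 0.073) were not called with airway markers in the model (adjusted p = 0.239, 0.216 and 0.249, edgeR).

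Of 19 amino acid transporters, 4 fell and 0 rose by edgeR, and the list's median log2 fold change was -0.062. These were Slc38a1 (from 38.2 ± 6.08 CPM at 12 weeks to 14.5 ± 3.58 at 68 weeks, log2 fold change -1.39 ± 0.18, adjusted p = 0.0068) and Slc1a5 (from 43.1 ± 9.23 CPM at 12 weeks to 23.9 ± 4.73 at 68 weeks, log2 fold change -0.85 ± 0.17, adjusted p = 0.0341), both glutamine carriers, the glutamate carrier gene Slc1a3 (-1.03 ± 0.15) and Slc38a4 (-0.85 ± 0.12). Adjusted over the list alone, 4 fell and 1 rose. The transporter list was lower by camera (adjusted p = 0.0155), with adjusted p = 0.486 with an estimated correlation. With airway markers in the model, log2 fold changes were -1.40 ± 0.22 for Slc38a1 and -1.03 ± 0.12 for Slc38a4, which stayed called, and -1.06 ± 0.20 for Slc1a3 and -0.61 ± 0.17 for Slc1a5, which were no longer called (adjusted p = 0.068 and 0.212, edgeR). Of 29 glutamine and glutamate genes, 1 was higher over all genes and adjusted over the list alone, the GABA transaminase gene Abat (0.80 ± 0.16). Glul (-0.073 ± 0.076), Glud1 (-0.024 ± 0.049) and the transporter gene Slc38a2 (0.16 ± 0.10) were not called.

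Of 19 cardiac stress and fetal genes, Myh7, the beta-myosin heavy chain gene, rose from 277 ± 70 CPM at 12 weeks to 493 ± 56.6 at 68 weeks (log2 fold change 0.83 ± 0.17, adjusted p = 0.0341), and 4 rose adjusted over the list alone. The log2 fold change of Myh7 was 0.73 ± 0.19 with airway markers in the model (adjusted p = 0.173, edgeR). It was 0.39 in the 4 libraries with the fewest airway counts, 1 against 3, and 1.10 in the 4 with the most, 3 against 1. Myh7 stood at 368 CPM in 12-week replicate 4, low in airway counts, against 198 to 278 CPM in the other 3. Nppa (0.15 ± 0.32), Nppb (0.82 ± 0.31) and Myh6 (0.047 ± 0.068) were not called. In 68-week replicate 4, the list members Ankrd1, Acta1 and Nppb stood at 2036, 1285 and 560 CPM. In 68-week replicates 1 to 3 they stood at 947 to 1251, 250 to 600 and 234 to 300 CPM. At 12 weeks they stood at 607 to 736, 354 to 472 and 110 to 240 CPM. Myh7 was not highest in 68-week replicate 4, at 522 CPM against 527 in 68-week replicate 3. Of 32 genes of calcium handling and ion channels, 2 rose and 0 fell, among them the sodium-calcium exchanger gene Slc8a1 (0.51 ± 0.062), and 4 rose and 1 fell adjusted over the list alone. Of 25 immediate early genes, 5 rose and 0 fell, with 8 and 0 adjusted over the list alone, among them Jun (0.60 ± 0.082), Fosl2 (0.59 ± 0.065), Nr4a1 (0.79 ± 0.13) and Ier3 (0.63 ± 0.12). Slc8a1 (0.48 ± 0.083) and Fosl2 (0.52 ± 0.076) stayed called with airway markers in the model, and Jun (0.55 ± 0.11), Nr4a1 (0.77 ± 0.17) and Ier3 (0.48 ± 0.13) did not. Camera placed these 3 lists higher with adjusted p = 0.000371, 0.0344 and 5.7e-06, and adjusted p = 0.486 for each with an estimated correlation. Heat shock genes (0 of 20 called, 5 adjusted over the list alone; adjusted p = 2.94e-06) and sarcomere genes (0 of 20 called, 2 adjusted over the list alone; adjusted p = 0.00166) were also higher by camera, each with adjusted p = 0.486 with an estimated correlation. Mitochondrially encoded mRNAs (0 of 13 called, 0 adjusted over the list alone; adjusted p = 0.00772 by camera and 0.701 with an estimated correlation), ribosomal protein genes (0 of 51, 0 adjusted over the list alone; adjusted p = 0.0046 and 0.77) and glycolysis genes (adjusted p = 0.0154 and 0.649) were higher by camera. The mitochondrial share of counts was 7.41% and 8.07% in 12-week replicates 1 and 2, against 10.1% to 12.1% in the other 6 libraries, and mt-Co1 stood at 34582 and 41287 CPM there against 51379 to 60227 CPM. Of 24 glycolysis genes, Pfkl rose (0.24 ± 0.05) and Pfkfb3 fell (-1.17 ± 0.21), as they did adjusted over the list alone, and neither was called with airway markers in the model (0.19 ± 0.065 and -1.11 ± 0.26).

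Among clock genes, both directions were seen. Per2 (1.06 ± 0.13), Ciart (1.06 ± 0.22) and Cry1 (0.51 ± 0.11) rose and Arntl, which encodes their activator BMAL1, fell (-1.13 ± 0.19), of 20 measured. Adjusted over the list alone, 9 rose and 4 fell. The list was higher by camera (adjusted p = 0.00166), with adjusted p = 0.486 with an estimated correlation. Per2 stayed called with airway markers in the model (0.88 ± 0.14), and Ciart (0.93 ± 0.27), Cry1 (0.32 ± 0.11) and Arntl (-0.84 ± 0.17) did not. The labels give no time of day for the samples.

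Of 41 extracellular matrix genes, 6 fell and 1 rose, with 15 and 8 adjusted over the list alone. Elastin (Eln, -1.53 ± 0.29), fibrillin (Fbn1, -0.66 ± 0.13), the crosslinking enzyme gene Lox (-0.75 ± 0.13) and Col1a1 (-0.73 ± 0.16) fell, Timp3 rose (0.26 ± 0.049), and Col3a1 was not called (-0.64 ± 0.15). Camera gave adjusted p = 0.00772 for this list, and adjusted p = 0.719 with an estimated correlation. With airway markers in the model, edgeR called 0 of the 41 genes and the list did not pass by camera (adjusted p = 0.142). Log2 fold changes were then -0.73 ± 0.19 for Lox, -0.54 ± 0.15 for Fbn1, -1.20 ± 0.42 for Eln, -0.53 ± 0.19 for Col1a1 and 0.25 ± 0.067 for Timp3. Between the single 12-week library with few airway counts, replicate 4, and the 3 such libraries at 68 weeks, they were -0.42, -0.62, -0.62, -0.46 and 0.26. Airway counts were high in 3 libraries at 12 weeks against 1 at 68 weeks. Of the adipocyte markers, 4 fell, with 9 adjusted over the list alone, including Adipoq (-1.86 ± 0.35), Cidec (-1.95 ± 0.37), Cfd (-1.71 ± 0.32) and Car3 (-1.80 ± 0.39). Of the 12, 0 were called with airway markers in the model, these 4 having log2 fold changes of -1.82 ± 0.42, -1.86 ± 0.42, -1.11 ± 0.33 and -1.49 ± 0.48. Without 12-week replicate 4, Adipoq (-1.74), Cidec (-1.71) and Car3 (-1.88) were no longer called (adjusted p = 0.0547, 0.0529 and 0.0607, edgeR). Cfd stayed called (-1.92, adjusted p = 0.0135, edgeR). The brown fat gene Ucp1 stood at 65.3 to 369 CPM of the total counts at 12 weeks and at 0.867 to 54.8 at 68 weeks.

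Among immune markers, the B cell genes Cd79a (-2.17 ± 0.41) and Cd79b (-1.96 ± 0.41), the T cell receptor gene Trac (-1.04 ± 0.22) and the macrophage receptor gene Cx3cr1 (-1.62 ± 0.22) fell, against the rise of Ighg2c. Cx3cr1 (-1.73 ± 0.28) and Ighg2c (2.68 ± 0.13) stayed called with airway markers in the model, and Cd79a (-1.69 ± 0.52, adjusted p = 0.247, edgeR), Cd79b (-1.74 ± 0.55) and Trac (-0.96 ± 0.27) did not. Cd79a stood at 1.06 to 1.94 CPM in the 3 libraries at 12 weeks with high airway counts and at 0.469 CPM in replicate 4. The lists of B and plasma cells, T and NK cells and macrophages did not pass by camera (adjusted p = 0.835, 0.0705 and 0.0925). Of 30 interferon response genes, Oasl2 alone was called (-0.46 ± 0.10, or -0.45 ± 0.14 and not called with airway markers in the model) and 4 fell adjusted over the list alone. That list had adjusted p = 2.94e-06 by camera and adjusted p = 0.512 with an estimated correlation. Neutrophil markers (0 of 7 called, 5 adjusted over the list alone; median log2 fold change -1.96), Schwann cell markers (0 of 9 called, 5 adjusted over the list alone; -0.56) and lung and thymus markers (0 of 6 called, 4 adjusted over the list alone; -1.83) were lower by camera. Each had adjusted p = 0.486 with an estimated correlation. The lung and thymus list holds Scgb1a1, Scgb3a2 and Sftpa1, and the neutrophil list Ltf, all among the leading genes of the first principal component. The neutrophil gene S100a8 stood at 4.34 and 9.38 CPM in 12-week replicates 2 and 3, and at 0.913 and 2.38 CPM in replicates 1 and 4. At 68 weeks it stood at 0.506 to 1.48 CPM. Of 49 nuclear genes of oxidative phosphorylation and 31 of fatty acid oxidation, 0 were called by edgeR, and 0 and 2 adjusted over the list alone.

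In all, camera called 17 of 45 lists, 9 higher and 8 lower. With an estimated correlation and with fry, 0 lists were called. Before adjustment, 21 lists had p under 0.05 by camera. With airway markers in the model, camera called 10 lists, 7 of them among the 17, and 0 with an estimated correlation. The 3 others were fatty acid oxidation (lower, adjusted p = 0.00168, and 0.759 with an estimated correlation), nuclear oxidative phosphorylation (lower, 0.0071 and 0.759) and developmental regulators (higher, 0.0406 and 0.551). The 10 that no longer passed were glycolysis, mitochondrially encoded mRNAs, sarcomere, calcium handling, extracellular matrix, clock, Hox, ribosomal protein, neutrophil and Schwann cell genes, with adjusted p from 0.0745 to 0.87.

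The authors' deposited tables listed 3433 regions with H3K27me3 unique to 68 weeks, covering 1034434 bases, and 1164 unique to 12 weeks, covering 358775 bases. Their median widths were 267 bases at 68 weeks and 268 at 12 weeks. Single genes could hold several regions, Pde11a being linked to 10 of the 68-week list, and 87 genes were linked to regions of both ages. The 68-week list was longer by a factor of 2.95, from 1.4 on chromosome X, with 5 and 7 regions, to 7.31 on chromosome 16, with 16 and 117. Regions of the lists overlapped 0 times, as lists of unique regions must, and 4 regions of the 12-week list lay within 1 kb of a 68-week region. The count of each list depends on the authors' threshold and library depth, which could not be examined, and no test between ages was possible.

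Whether the leading regions of either list were repeats was not tested. By the authors' score, the 12-week list was led by a region with no linked gene on chromosome 9, 3000269 to 3000640 (score 535). Of the 12-week regions, 14 lay within the first 3.1 Mb of that chromosome. Of the 10 highest, 7 were linked there to the predicted genes Gm10722, Gm10718, Gm10719, Gm10721 and Gm11168. Gm10800 on chromosome 2, 98497010 to 98497553, had a score of 281. The 68-week list was led by regions linked to Mug-ps1 (chromosome 6, 122217883 to 122218148, score 26.7), to Gm10222 with 6 further predicted genes (chromosome 1, 24650762 to 24655157, score 20.7) and to Rn18s-rs5 (chromosome 17, 40157871 to 40158093, score 18.5). Vipr1, Otulinl and Plut were also linked to regions among the 10 highest in the authors' deposited table.

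Developmental genes were linked to 12-week regions more often than to 68-week regions. Each list's share was compared between the 462 genes linked only at 12 weeks and the 1186 linked only at 68 weeks, whether or not measured in RNA. Of 82 developmental regulators known as Polycomb targets, 18 were linked only at 12 weeks, including Pax6, Shh, Gata3, Tbx3, Cdkn2a and Cdkn2b. Linked only at 68 weeks were 3, namely Bmp7, Pax2 and Sox11 (Fisher's exact test, adjusted p = 2.2e-06 over 45 lists). A further 5 were linked at both ages and were left out of the test. Of 39 Hox genes, 8 were linked only at 12 weeks and 0 only at 68 weeks (adjusted p = 0.000821, Fisher's exact test). The other 43 lists did not pass. In RNA, 8 Hox genes were measured and Hoxa5 fell (-1.22 ± 0.24, or -1.44 ± 0.28 and not called with airway markers in the model), with 3 lower adjusted over the list alone. Hoxa5 was not among the 8 linked Hox genes. The Hox list was lower by camera (adjusted p = 0.0301), with adjusted p = 0.486 with an estimated correlation. Of 37 developmental regulators measured, 1 rose and Pax5 fell, with 3 and 2 adjusted over the list alone, and the list's median log2 fold change was 0.048 against a mean of -0.043 (adjusted p = 0.441 by camera).

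Genes linked to regions unique to 12 weeks were over-represented among genes that rose by 68 weeks. Of 230 such genes tested, 19 were among the 256 higher genes, against 3.69 expected (odds ratio 5.88, 95% confidence interval 3.41 to 9.62, adjusted p = 5.77e-08, Fisher's exact test). They were Cdkn2a, Cds1, Cdh22, Bnc2, Scn4b, Rab6b, Cxcl14, Cacna1s, Kcnip1, Vgll2, Osgin1, Unc5a, Atp2b2, Rap1gap, Gsg1l, Tmem266, Dock3, Shank1 and Gm10800, printed in full after their values were seen. Of these, Gsg1l, Tmem266, Dock3 and Shank1 were also linked to 68-week regions and are counted in both overlaps. Without the genes linked at both ages, 15 of 194 were higher (odds ratio 5.39, adjusted p = 2.84e-06, Fisher's exact test). The sodium channel subunit gene Scn4b rose from 97.4 ± 3.87 CPM at 12 weeks to 166 ± 15.2 at 68 weeks, the zinc finger gene Bnc2 from 3.24 ± 0.362 CPM at 12 weeks to 7.06 ± 0.643 at 68 weeks, and the lipid synthesis gene Cds1 from 7.93 ± 0.973 CPM at 12 weeks to 24.2 ± 2.77 at 68 weeks, with log2 fold changes of 0.77 ± 0.068, 1.12 ± 0.11 and 1.60 ± 0.11. The region linked to Cdkn2a lay on chromosome 4, 89205847 to 89206061, that linked to Cds1 on chromosome 5, 101967154 to 101967373 and that linked to Bnc2 on chromosome 4, 84589238 to 84589538, in the authors' coordinates. Of the 195 lower genes, 2 were linked to 12-week regions, Pax5 and Scd1 (odds ratio 0.706, adjusted p = 1, Fisher's exact test).

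**Figure D3:**
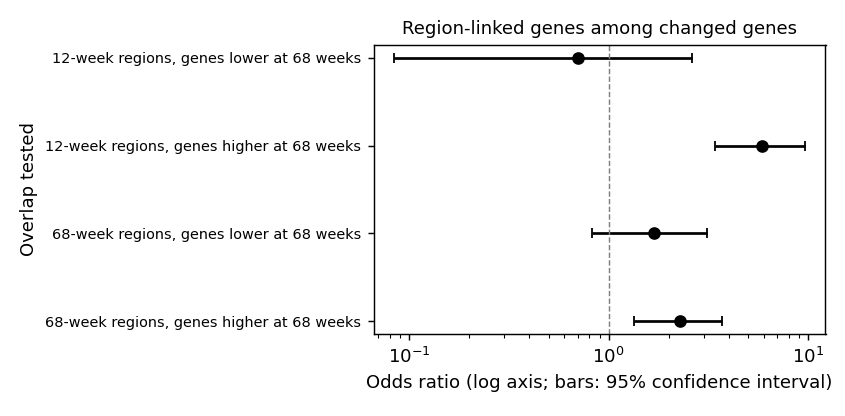
Odds ratio (x axis, log scale) with 95% confidence interval for the overlap of genes linked to 12-week or 68-week regions with genes higher or lower at 68 weeks (y axis). The odds ratio for 12-week regions and higher genes was 5.88, and for 68-week regions and higher genes 2.28.

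For regions unique to 68 weeks, 19 of 551 linked genes were among the higher genes (odds ratio 2.28, adjusted p = 0.00535, Fisher's exact test). Acsl6 (0.95 ± 0.08), Myo5b (0.46 ± 0.047), Pde11a (1.79 ± 0.24) and Myh7 were among them. Without the genes also linked to 12-week regions, 15 of 515 were higher and the overlap did not pass (odds ratio 1.89, adjusted p = 0.0587, Fisher's exact test). Genes linked to 68-week regions were long, with a median span of 67 kb against 20.9 kb over all tested genes. Against genes matched on span and expression the ratio of observed to expected was 1.61 (two-sided permutation p = 0.0468 over 10000 random draws of genes). The overlap did not pass without 12-week replicate 1, 2 or 3, with odds ratios of 2.01, 2.03 and 2.11 (Fisher's exact test). Of the lower genes, 11 were linked to 68-week regions (odds ratio 1.68, adjusted p = 0.182, Fisher's exact test), among them Slc38a1, whose region lay on chromosome 15, 96538321 to 96539318 in the authors' coordinates. As a set, the genes linked to 12-week regions were higher by camera (adjusted p = 0.00214), with a median log2 fold change of 0.031 and adjusted p = 0.307 with an estimated correlation.

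**Figure D4:**
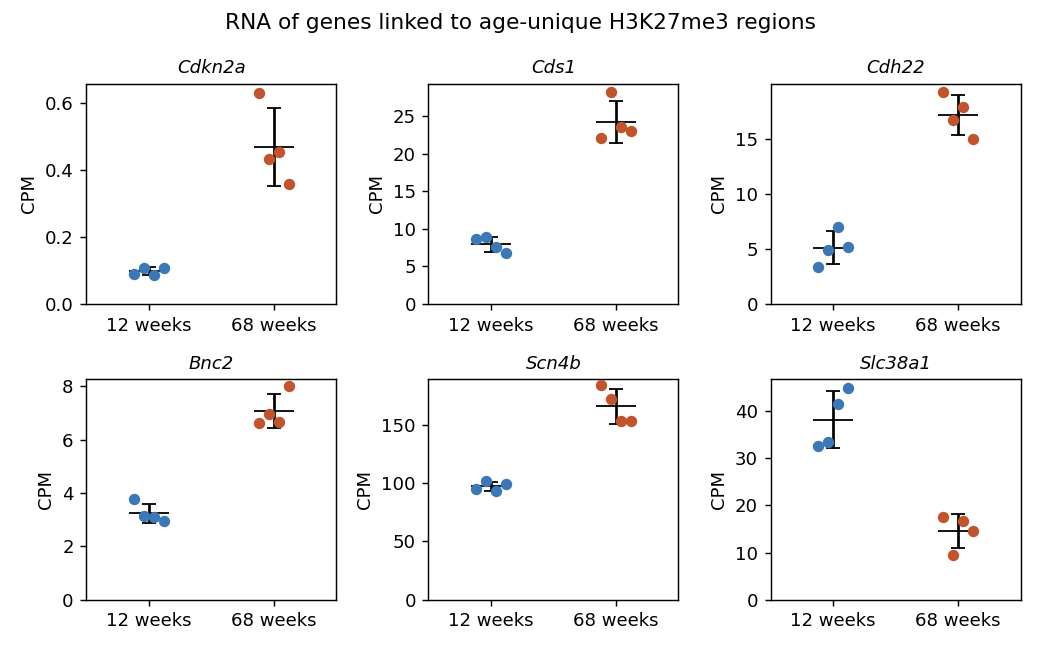
CPM (y axis) of 6 genes linked to age-unique regions in the 4 libraries of each age (x axis), with mean and SD. Cdkn2a, Cds1, Cdh22, Bnc2 and Scn4b were linked to 12-week regions and Slc38a1 to a 68-week region, and each gene's 4 libraries of 1 age lay apart from the other 4.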

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

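In 32 of 444 groups of 4 libraries examined, 1 library lay far from the other 3 by Dixon's criterion, where chance gives 22.2. The values reported are log2 CPM of that library, with the range of the other 3 in parentheses. In 12-week replicate 1, these were Klk1b26 at -1.59 (-1 to -0.9), Lpl at 12.28 (12.42 to 12.42), Oasl2 at 3.85 (3.58 to 3.6), Fosl2 at 5.94 (6.15 to 6.17), Pdgfrb at 6.65 (6.15 to 6.23), Car3 at 7.87 (6.95 to 7.08), Tnni2 at 0.45 (0.91 to 0.99). In 12-week replicate 4, these were Pde11a at 1.91 (1.19 to 1.26), Kif23 at -1.1 (-0.35 to -0.25), Gja5 at 5.4 (4.39 to 4.47). In 12-week replicate 2, these were Kdm6a at 4.46 (4.67 to 4.71), Ndufa2 at 7.48 (7.28 to 7.31), Jun at 6.48 (6.16 to 6.19), Pdgfra at 6 (6.1 to 6.11), Gsn at 10.23 (10.29 to 10.31). In 68-week replicate 4, these were Edn3 at 4.42 (3.11 to 3.25), Ier3 at 5.4 (5.31 to 5.33), Gzma at -3.35 (-1.94 to -1.81). In 68-week replicate 2, these were Cd209f at 1.51 (2.21 to 2.29), Sln at 5.81 (7.16 to 7.29), Col1a1 at 6.95 (7.48 to 7.54), Pdgfra at 5.62 (5.88 to 5.9). In 68-week replicate 3, these were Ndufa2 at 7.18 (7.28 to 7.29), Cspg4 at 5.49 (5.31 to 5.34), Sftpa1 at 0.63 (-3.88 to -3.88), Sftpb at -0.09 (-2.51 to -2.21). In 68-week replicate 1, these were mt-Nd3 at 5.75 (5.56 to 5.58), Myh7 at 8.67 (9.01 to 9.04), Tyms at 0.64 (1 to 1.06), Cx3cr1 at 1.53 (0.52 to 0.69).

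The mean log2 CPM of the airway markers was 3.1 in 68-week replicate 3, against -2.91 to -2.7 in the other 3 libraries of that age. The same library carried the surfactant genes Sftpa1 and Sftpb above the other 3. The marker lists behind this value were written after the principal components were seen.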

How the results depend on the processing

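The airway settings, and DESeq2 on the genes kept by edgeR, were chosen after seeing the data. The 256 higher and 195 lower genes became 568 higher and 439 lower with DESeq2 under its own filter, with 16415 of 30702 genes left, 557 higher and 455 lower with DESeq2 on the genes kept by edgeR, 57 higher and 15 lower at an adjusted p under 0.01, and 138 higher and 118 lower with at least a 1.5-fold change. Fewer libraries or more model terms gave 61 higher and 14 lower with airway markers as a covariate, 10 higher and 23 lower in the 4 libraries with the fewest airway counts (1 against 3) and 4 higher and 1 lower in the 4 with the most (3 against 1). Without 1 library, 117 to 209 genes were higher and 52 to 154 lower. Higher genes fell by over 1.5-fold without 12-week replicate 1, 2 or 3 or 68-week replicate 2, 3 or 4, and lower genes without any library but 68-week replicate 3. The other normalizations and filters kept both counts within 1.5-fold, and 0 of the 451 genes changed sign in any setting, which for subsets of libraries follows largely from their selection, since all separated the ages.

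With the replicate block, 112 higher and 48 lower genes were called. The title numbers were not shown to pair the libraries: same-number correlations of deviations were -0.24, -0.04, 0.04 and 0.33. Of all libraries, only 68-week replicate 4 correlated best with its own number. The block also lost the overlap of 68-week regions with higher genes (odds ratio 2.17).

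The overlap of 12-week regions with higher genes passed in all settings run, with ratios from 3.63 to 13.3. That of 68-week regions with higher genes ended with regions at or above each list's median score (1.91) and at adjusted p under 0.01 (1.56). It also ended without 12-week replicate 1, 2 or 3, the range without 1 library being 2.01 to 2.66. For lower genes, 68-week regions passed with DESeq2 (2.45, or 2.19 on the genes kept by edgeR) and without 68-week replicate 3, with a range without 1 library of 0.529 to 2.41. The ratio of 12-week regions with lower genes, not past the threshold, was 1.9 with DESeq2, 1.9 with DESeq2 on the genes kept by edgeR, and 0 to 1.85 without 1 library. In 6 settings that overlap was 0 genes, a ratio of 0, 2 of them without 1 library.

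Camera called 17 lists, 0 with an estimated correlation, 0 with fry, 10 with the airway covariate (7 of the 17 and 3 others) and 13 to 21 without 1 library. Among the 4 libraries with the fewest airway counts, where 12-week replicate 4 alone stands for its age, mitochondrially encoded mRNAs (adjusted p = 0.558) and clock genes (adjusted p = 0.948) changed sign by camera. Counting regions within 1 kb as shared moved the shared regions from 0 to 4. The region ratio of 2.95 became 3.7 and 4.16 at score minimums of 5 and 8, chosen after seeing the data. Links by distance to gene starts or gene bodies were not run, because the build of the regions was not established.

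Log2 values of uncalled named genes changed sign in the 4 libraries with the fewest airway counts for Ndufa2 (0.0043), mt-Cytb (-0.054), mt-Co3 (-0.13), Hells (0.22), Cd74 (0.14), Ciita (0.083), Prox1 (0.039), Mylk (0.31), Lck (0.40), Hba-a2 (1.78), Alas2 (1.59), Hbb-bs (1.76), Glud1 (0.044), Nppa (-0.21). In the 4 libraries with the most this held for Rbbp7 (-0.00062), Kif23 (-0.22), Gja5 (0.10), Sln (0.28), Stard10 (0.33), Prox1 (0.035), Slc4a1 (-3.03), Slc38a2 (-0.10), Myh6 (-0.066). With DESeq2 this held for Eed (0.0012). With the airway covariate this held for Prox1 (0.058), Slc4a1 (-0.76), Krt19 (0.048), Glud1 (0.016), Slc38a2 (-0.011). With library size alone this held for Myh6 (-0.011). With limma-voom this held for Slc4a1 (-0.0015). Without 1 library, values of genes that changed sign ran for Sln from -0.49 to 0.016, Stard10 from -0.29 to 0.057, Slc4a1 from -1.73 to 1.82, Alas2 from -2.17 to 0.11, Hbb-bs from -2.14 to 0.18, Eed from -0.10 to 0.058, Kdm6b from -0.12 to 0.0047, Glud1 from -0.046 to 0.0019, Nppa from -0.15 to 0.39. The cause was not tested.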

Other observations

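The tests of airway tissue carried into samples, of exchanged labels, of Hox clusters and scores, and of genes linked at either age were chosen after the result was seen, as were all airway settings.

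Single genes of one-carbon, redox and stress metabolism changed while their lists were not called by camera. Nnmt, which methylates nicotinamide, fell (-0.79 ± 0.12) and the methionine synthase gene Mtr rose (0.46 ± 0.072), of 21 methionine cycle genes measured. The pyruvate carboxylase gene Pcx fell (-0.67 ± 0.12). Chac1, which degrades glutathione, fell (-1.35 ± 0.29) while Ddit3 rose (0.37 ± 0.082). Of 26 antioxidant genes, Gsta2 (2.00 ± 0.27), Gstm2 (0.30 ± 0.061) and Nqo1 (0.34 ± 0.071) rose, adjusted p by camera being 0.197. Gsta2 and Gstm2 have close paralogs, so their counts are uncertain. Of 17 complement genes, C1s1 (0.42 ± 0.073) and C4b (0.54 ± 0.11) rose and Cfd, also an adipocyte marker, fell, with a list median of 0.09 and mean of -0.019. Of 26 genes of cell cycle arrest and secretion, Cdkn2a and the chemokine gene Ccl8 (1.47 ± 0.20) rose, Trp53inp1 fell (-0.67 ± 0.094), and Cdkn1a was not called (-0.31 ± 0.16). With airway markers in the model, Nnmt (-0.88 ± 0.14), Gsta2 (2.09 ± 0.34) and Ccl8 (1.51 ± 0.25) stayed called and the others named here did not. Among those not called, Mtr (0.44 ± 0.094) and Pcx (-0.56 ± 0.14) kept most of their log2 fold change.

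Of 17 Pcdhb genes measured, which encode clustered protocadherins, 6 rose and 0 fell by edgeR, with log2 fold changes of 0.40 to 1.37 in the called genes. This group was noticed after its values were seen, and its members share sequence, so their counts are uncertain. It was not tested as a list.

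The split by age gave the most changed genes but not the most changed lists. Of 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the split by age with 451, and the highest other gave 254. That other split parted the 4 libraries with the most airway counts from the rest. With 35 splits, 1 is the fewest that can give as many, for an exact permutation p of 0.0286, so chance was not excluded. For lists, 9 of the 35 splits gave as many as the 17 of the real split, the highest other being 21.

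Airway epithelial transcripts in heart libraries may come from airway tissue carried into some samples. Markers of secretory, ciliated and basal cells, 3 of 3 classes, ranked the same 4 libraries highest, with Scgb1a1 at 351 and Bpifa1 at 795 CPM of the total counts in 12-week replicate 1, while the alveolar gene Sftpc stayed at or below 2.58 CPM in all 8. Exchanging the labels of 12-week replicate 4 and 68-week replicate 3 called 254 genes by edgeR against 451 as labelled. The other 15 exchanges called 0 by edgeR, and these counts argue against a swap of these libraries. The 254 included 19 of 20 airway markers and 0 of the 451. That 0 follows largely from selection, since all 451 separated the labelled ages, and is no evidence on a swap. The exchanges are among the 35 splits above and are not separate from them. An earlier comparison of those 2 libraries with the other 6, over 735 genes, put 51.7% and 54.4% of genes nearer to their own age, and it was set aside because airway content followed age among the 6. With airway markers in the model, the median share of the log2 fold change kept was 0.942 for lower and 0.965 for higher genes, while the median SE rose from 0.127 to 0.156 and from 0.108 to 0.132 and 13 and 59 calls were kept, so folds were largely kept while errors grew. Those genes were selected for separating the ages, and fat and other tissue differing between ages stay open, as does age itself.

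Genes linked to regions unique to 12 weeks were frequent among genes higher at 68 weeks. Against genes matched on genomic span and expression, the observed overlap exceeded the expected by a ratio of 4.23 (two-sided permutation p = 0.0002, the smallest that 10000 draws can give), which argues against gene length as the whole cause. Genes linked only at 12 weeks were higher more often than genes linked only at 68 weeks, 15 of 194 against 15 of 515. The odds ratio was 2.79 (95% confidence interval 1.24 to 6.26, Fisher's exact p = 0.0103), which argues against an equal rise whichever the age. Of genes linked at both ages, 4 of 36 were higher (odds ratio 7.76, adjusted p = 0.00638, Fisher's exact test). A rise of linked genes at either age, to differing degrees, stays open. The build of the regions, the linking rule and whether regions such as that of Gm10800 are repeats stay open, and age itself stays open. Whether these genes lost the mark was not tested, since no region had a value per library.

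Hox genes were linked to regions unique to 12 weeks and to none unique to 68 weeks. In RNA, Hoxa5 fell and the list of 8 measured Hox genes was lower by camera (adjusted p = 0.0301, and 0.486 with an estimated correlation). Hoxa5 was linked to no region of either list, so the 8 measured genes were not the 8 linked ones. The 12-week regions lay in 4 of 4 Hox clusters, which argues against 1 cluster counted many times. Among regions scoring at or above the median of their list, 5 Hox genes were linked at 12 weeks and 0 at 68 weeks (Fisher's exact p = 0.00157). This argues against regions below the median alone. The scores of these Hox regions ran from 4.71 to 6.14, against a 12-week median of 4.50. Hoxc5 and Hoxc6 shared regions among them, as did Hoxa3 and Hoxa6. Genes of a cluster are neighbours and share regions, so they are not independent, and differences in depth or background between the CUT&RUN libraries stay open and untested, as does age itself.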
